A study of Branchiostoma lanceolatum with 8 samples.

How the data were processed

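RNA was measured in explants of ectoderm, the outer embryonic layer, cut from embryos of the amphioxus *Branchiostoma lanceolatum*, an invertebrate chordate. The labels give 4 groups of 2 libraries each, 8 in all: control and Activin-treated explants, collected at 11 and at 19 hours post fertilization (hpf). Activin, a ligand of the TGF-beta family, was used as human recombinant protein at 50 ng/mL, per the labels. Each replicate mixed explants from different fertilizations, per the series design, and libraries were made from poly(A) RNA. Replicate 1 and 2 are numbers in the titles, and no label ties a number to a shared fertilization across groups.

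The authors deposited 2 tables of their own comparisons, 1 per time, and values per library were not used here. Reads were handled with HISAT2, featureCounts and edgeR, per the submitters' processing notes, with versions, genome build and annotation not given in the sources used here. The column names, per the file headers, are those of a DESeq2 results table, a tool that the submitters' processing notes do not name, so which tool made the final values is open. The mean column is a signal of depth-normalized counts averaged over libraries by the authors, per the file headers. The log2 fold change and its standard error are log2 values between treatments, by the authors, per the file headers. The test column is a score, the Wald statistic deposited by the authors. It equalled the log2 fold change divided by its standard error in every row. The p-value columns were deposited by the authors as a raw and an adjusted p, and the adjusted one equalled a Benjamini-Hochberg adjustment over exactly the deposited rows.

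The headers do not state which treatment is the numerator of the fold change. A positive value was read as higher in Activin because LEFTY2, CHRD and GSC, targets of Nodal/Activin signalling in other chordates, were positive at both times. Every direction given here rests on that reading, and the Nodal/Activin and organizer lists are therefore no independent evidence of direction. The BMP list holds CHRD too and shares this limit. Gene names are those that the deposited tables pair with each identifier, and they are human-style symbols. They covered 10697 of 15793 rows at 11 hpf and 11336 of 16733 rows at 19 hpf. Labels of the form NA, Hypp, ENSG or a clone name were not counted as names, a rule completed after the values were seen. Several rows can share a symbol, and reads shared between such copies could move counts from one to another, so identifiers are given where they do. The reference gene table at hand holds another assembly with other identifiers, so it was not used and no coordinates are printed.

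Depth per library is unknown from these tables. The mean normalized counts summed to 9146020 at 11 hpf and 10891500 at 19 hpf. Precision was read from the deposited standard errors: the median was 1.604 on the log2 scale for genes with a mean under 20 normalized counts at 11 hpf and 0.352 for those of 1000 or more. At 19 hpf the same medians were 1.74 and 0.329. With 2 libraries a group, the p-values refer to the spread between pooled explant samples as the authors' model estimated it. The lowest standard error of any gene, 0.325 at 11 hpf and 0.295 at 19 hpf, lay close to the medians of abundant genes. The errors may therefore reflect a spread shared over genes more than that of each gene.

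The edgeR quasi-likelihood fit planned before the data were examined was not run, since it needs counts per library. For tables that hold only fold changes and p-values the plan was to use the authors' values with an adjusted p below 0.05 and no refit, which is what was done. Group means were rebuilt from the deposited mean and fold change, assuming equal weight for both groups. A fold is not given as readable where the rebuilt mean of the lower group was under 3 normalized counts, a floor set after the values were seen. The difference between times was planned to stay untested. A Wald test of that difference, from both standard errors with Benjamini-Hochberg adjustment, was added once the tables proved to hold standard errors. It covered 13528 genes in both tables, and the 2 times share no library. It was tested on simulated data for 13528 genes with 50 genes changed at each size. With the deposited standard errors as noise, it recovered 0% of log2 differences of 1 and 16% of those of 2. It recovered 54% of differences of 3 and 60% of those of 4, with 2 false calls among 67. Far fewer genes changed in the simulation than the 2268 called in the data. The adjusted threshold was therefore stricter there, so these rates may understate recovery in the data. No test of 19 against 11 hpf within a treatment was made, because the tables were normalized separately, and rebuilt means of both times were set side by side only to weigh a slower decline of transcripts.

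The 16 gene lists and their matching rule were fixed before the data were examined. They were Nodal/Activin pathway, dorsal organizer, mesoderm, endoderm, neural plate regulators, neuronal differentiation, epidermis and non-neural ectoderm, BMP, FGF/ERK and Wnt pathways, retinoic acid and Hox, muscle effectors, motile cilia, germline and maternal genes, cell cycle, and stress and cell death. Matches to the organizer and endoderm lists that were plainly other genes were dropped after the matches were seen. Lists can share members, such as CHRD in organizer and BMP, OTX2 in organizer and neural plate, and FOXA1 in organizer and endoderm. Their tests are therefore not independent of each other. Each list was compared with all other genes by limma's cameraPR on the deposited Wald statistic, two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the 16 lists. An estimated correlation needs values per library and was not computed. Preset correlations of 0.05 and 0.1, the rank version of the test and a background of genes with symbols only were added after the data were seen. The Wald statistic was skewed, with a mean of -0.83 and a median of 0.10 at 11 hpf and -0.74 and 0.10 at 19 hpf, so a list that does not move can score as higher. The rank version is therefore given beside the main test for each list that passed it, and no list that missed the main test passed the rank version. In addition 12 families defined by symbol were counted after the values were seen.

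Named genes followed a rule fixed before the data were examined. Per time it took the 12 named genes with the largest rise and the 12 with the largest fall among those with an adjusted p below 0.05 and at least 1 log2 CPM, taken here from the deposited means. It added up to 4 members per list with the smallest p, the 5 genes per direction with the smallest p for the difference between times, and a set of key developmental genes whatever they did. Except among the key genes, rows of the same symbol counted once, by the largest change or the smallest p. Other copies of such genes can differ and are mostly not given. The part of the rule that asks for both libraries to move together could not be applied to tables without libraries. Nodal and Vent, 2 of the key genes, were not analysed here. Some genes that the rule selected are not reported here and were not replaced, though they count as members of their lists. Alternatives tried were an adjusted p below 0.01, a fold of at least 2, and, chosen after seeing the data, 5 other scalings and a filter on rows with a mean of 20 or more. The scalings subtracted the median of all genes, the median of genes with a mean of 100 or more, the median of cytosolic ribosomal protein genes, or the offset of the upper quartile or of the total of the rebuilt group means. Fold changes were then tested again from the deposited standard errors. Software was Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and scipy 1.17.1, and R 4.3.3 with limma 3.58.1.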

Results

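RNA levels were measured by sequencing in ectodermal explants of amphioxus, pieces of the layer that forms epidermis and nervous system. Explants were left untreated or exposed to Activin, a TGF-beta family ligand that acts through the Nodal receptors, and collected at 11 or 19 hpf. Each of the 4 groups held 2 libraries of pooled explants. All fold changes, errors and adjusted p of single genes are those of the authors' deposited table for each time, with 15793 genes at 11 hpf and 16733 at 19 hpf, of which 13528 were in both. Fold changes are log2 values of Activin over control, and ± gives the authors' standard error of that value, with 2 libraries per group. Calls are genes with a Benjamini-Hochberg adjusted p below 0.05, as deposited by the authors, two-sided. Depth per library is unknown from these tables. Precision followed abundance: the standard error gave a 95% limit of 8.83-fold for genes under 20 normalized counts at 11 hpf and of 1.61-fold for those of 1000 or more. At 19 hpf these limits were 10.7-fold and 1.56-fold. The headers do not name the numerator, and a positive value was read as higher in Activin because LEFTY2, CHRD and GSC were positive at both times.

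The comparison at 11 hpf asked which genes differed between Activin-treated and control explants at the earlier time. In the authors' deposited table LEFTY2 (BL04376), a secreted Nodal antagonist, was 83.8-fold higher, at 6.39 ± 0.53, and CHRD (BL24510), a secreted BMP antagonist, was 24.01-fold higher, at 4.59 ± 0.43. Genes of the epidermis fell, among them KRT8 (BL15060), a keratin, 58.3-fold lower at -5.86 ± 0.37, and TFAP2D (BL23731), of the AP-2 family of ectodermal regulators, 62.2-fold lower at -5.96 ± 0.34. Motile cilia genes fell nearly as a block, 43 of 48. The neurogenic factor NEUROG3 (BL06125) rose 108-fold, at 6.75 ± 0.50.

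Of 9 measured genes of the Nodal/Activin pathway 5 rose, 0 fell and 4 did not pass, the same count as adjusted over the list alone. Beside LEFTY2, the authors' deposited table gave 5.02 ± 0.38 for SKI (BL02854), a repressor of SMAD activity, 3.55 ± 0.52 for the Nodal co-receptor CFC1 and 2.55 ± 0.60 for the inhibitory SMAD6. The list stood above other genes by limma's cameraPR, Benjamini-Hochberg adjusted p = 1.3e-04, and its rank version, adjusted p = 0.023, and its median of 1.74 kept its sign under all 5 other scalings. It is no independent evidence of direction, since LEFTY2 set the reading of the sign. Organizer genes went both ways, 5 higher and 6 lower of 15, also when adjusted over the list alone, with limma's cameraPR, Benjamini-Hochberg adjusted p = 0.45. GSC (BL18678), an organizer homeobox gene, rose by 2.77 ± 0.58 and OTX2, a regulator of anterior identity, by 3.39 ± 0.47. SHH, a signal of the midline, fell (-4.01 ± 0.48) and DKK3 (-3.87 ± 0.38).

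Germ layer lists did not pass at 11 hpf. Of 23 mesoderm genes 5 rose and 1 fell, with limma's cameraPR, Benjamini-Hochberg adjusted p = 0.084. SNAI2, a regulator of cell migration, rose by 4.39 ± 0.54 and RIPPLY2, a somite gene, by 4.26 ± 0.74, while EVX2, a homeobox gene, fell (-4.21 ± 0.65). Brachyury had 2 genes, T (BL23554) at -0.18 ± 0.65 and T (BL23557) at 0.07 ± 0.44 in the authors' deposited table, neither called. Of 11 endoderm genes 4 rose and 2 fell, with limma's cameraPR, Benjamini-Hochberg adjusted p = 0.20. FOXA1 rose by 1.43 ± 0.54, CDX4 (BL12756), a posterior homeobox gene, fell (-2.26 ± 0.52), HHEX fell (-2.71 ± 1.07), and FOXA2 stood at 0.91 ± 1.04, not called. The endoderm median of -0.22 had the opposite sign to its mean of 0.96 and to the test, and turned positive under upper-quartile and total-count scaling. The counts of both lists were the same when adjusted over the list alone.

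Neural plate regulators rose more often than they fell, 9 against 5 of 32, and 11 against 6 when adjusted over the list alone. ZIC1 rose by 3.16 ± 0.37 and SOX4 by 3.71 ± 0.45, both transcription factors of neural development, while SIX3, an anterior neural regulator, fell (-3.24 ± 0.35). The SOX2 genes stood at 2.93 ± 0.81 (BL03503), 0.81 ± 0.33 (BL16399) and 1.29 ± 0.38 (BL16400) in the authors' deposited table, and SOX1 at 2.47 ± 1.16, not called. The list passed limma's cameraPR, Benjamini-Hochberg adjusted p = 0.021, and the rank version, adjusted p = 0.026, but not with a preset correlation of 0.05, adjusted p = 0.17. Its median of 0.89 kept its sign under all 5 scalings. Neuronal differentiation genes split, 8 higher and 15 lower of 42, also when adjusted over the list alone, with limma's cameraPR, Benjamini-Hochberg adjusted p = 0.76. NEUROG3 and the neuronal RNA-binding gene ELAVL4 (BL11117), 17.8-fold higher at 4.15 ± 0.35, rose. The transmitter genes GAD2 (BL22766), for GABA synthesis, and SLC17A8, a glutamate transporter, fell (-4.78 ± 0.40 and -5.20 ± 0.49), and the neurogenic NEUROG2 (BL17845) (-3.97 ± 1.36), with an Activin mean under the floor of 3 counts. The median of the neuronal list was -0.16 and its mean -0.33 while the test pointed up, and the median turned positive under 3 scalings, the median of well measured genes, upper quartile and total count.

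Epidermis and non-neural ectoderm genes fell, 11 of 18, while 3 rose, also when adjusted over the list alone. GATA2, an ectodermal regulator, was 28.2-fold lower at -4.82 ± 0.36, KLF2 lay at -3.63 ± 0.36 and DLX1, a ventral ectoderm homeobox gene, at -2.31 ± 0.39 in the authors' deposited table. The 3 that rose, named after their values were seen, were TBX2 (BL14067) at 1.59 ± 0.34 and TP63, an epithelial regulator, at 2.28 ± 0.36 (BL04328) and 1.86 ± 0.46 (BL19570). The list passed limma's cameraPR, Benjamini-Hochberg adjusted p = 3.3e-05, and its rank version, adjusted p = 0.026, its median was -2.64, and its sign held under all 5 scalings. Of the 48 motile cilia genes 43 fell and 1 rose, also when adjusted over the list alone. FOXJ1 (BL13340), the main regulator of motile ciliogenesis, was 27.7-fold lower at -4.79 ± 0.42, and TEKT3 (BL11351), a tektin of the axoneme, 39.9-fold lower at -5.32 ± 0.35. DNAH3 (BL08114), an axonemal dynein heavy chain, lay at -4.89 ± 0.39 and TEKT1 at -3.81 ± 0.34 in the authors' deposited table. The gene that rose was DNAH9 (BL14190), 3.29 ± 0.92, named after its value was seen. The cilia list passed limma's cameraPR, Benjamini-Hochberg adjusted p = 3.4e-14, and its rank version, adjusted p = 1.3e-11, with a median of -2.21 that stayed negative under all 5 scalings.

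Germline and maternal genes rose, 7 of 17, while 0 fell, also when adjusted over the list alone. TDRD1 (BL06350), a Tudor protein of the piRNA pathway, rose by 2.62 ± 0.44, TDRD9 (BL12249) by 1.61 ± 0.38 and NANOS2, a translational repressor of germ cells, by 1.25 ± 0.44. Their list passed limma's cameraPR, Benjamini-Hochberg adjusted p = 0.021, and its rank version, adjusted p = 0.013, but not with a preset correlation of 0.05, adjusted p = 0.12, and its median of 0.95 kept its sign under all 5 scalings. Of 35 cell cycle genes 9 rose and 5 fell, also when adjusted over the list alone, with MCM5, a replication helicase subunit, at 3.21 ± 0.40, MCM6 at 3.04 ± 0.39 and RRM1, a ribonucleotide reductase subunit, at 2.44 ± 0.37 in the authors' deposited table. This list passed limma's cameraPR, Benjamini-Hochberg adjusted p = 0.035, but not its rank version, adjusted p = 0.19, a preset correlation of 0.05, adjusted p = 0.21, or a background of genes with a symbol, adjusted p = 0.065. Its median of 0.16 turned to -0.21 on ribosomal centring.

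Other signalling and effector lists did not pass at 11 hpf. BMP pathway genes numbered 7 higher and 5 lower of 23, with limma's cameraPR, Benjamini-Hochberg adjusted p = 0.34, a median of -0.27 and a mean of 0.30. TWSG1, a modulator of BMP, rose by 3.79 ± 0.57 and BAMBI, a pseudoreceptor, fell (-3.57 ± 0.47). BMP2 was 4.57 ± 0.96 for BL21413 and -1.93 ± 0.44 for BL12966 in the authors' deposited table, and BMP4 lay at -1.61 ± 0.62. FGF/ERK genes numbered 0 higher and 5 lower of 16, and 4 lower adjusted over the list alone, with limma's cameraPR, Benjamini-Hochberg adjusted p = 0.49. Under upper-quartile scaling 5 were higher and 4 lower, and under total-count scaling 6 and 4, so the split depends on the scaling. FGFR3 (BL14111), an FGF receptor, fell (-5.85 ± 0.52). The FGF median of 0.21 had the opposite sign to the mean of -0.63 and to the test. Wnt genes numbered 3 higher and 10 lower of 29, and 3 and 11 adjusted over the list alone, with limma's cameraPR, Benjamini-Hochberg adjusted p = 0.58. NOTUM (BL06981), a Wnt deacylase, fell (-5.35 ± 0.63) and the receptor FZD5 (-2.26 ± 0.33). Retinoic acid and Hox genes numbered 2 higher and 4 lower of 13, with limma's cameraPR, Benjamini-Hochberg adjusted p = 0.88, and ALDH1A2 (BL09708), a retinal dehydrogenase, fell (-3.28 ± 0.41). Muscle genes numbered 2 higher and 3 lower of 23, and 1 and 3 adjusted over the list alone, with limma's cameraPR, Benjamini-Hochberg adjusted p = 0.63, a median of 0.32 and a mean of -0.13. TPM1, a tropomyosin, fell (-5.14 ± 0.36) and CKM (BL09597), a creatine kinase, rose by 3.29 ± 0.38. Stress genes numbered 4 higher and 6 lower of 24, with limma's cameraPR, Benjamini-Hochberg adjusted p = 0.44. ATF4, a stress response factor, rose by 3.14 ± 0.39 and XBP1, of the unfolded protein response, fell (-3.04 ± 0.44). Medians of BMP, Wnt and retinoic acid genes turned positive under upper-quartile and total-count scaling, those of retinoic acid genes also on the median of well measured genes. Those of FGF, mesoderm and muscle genes turned negative on ribosomal centring. The larger side of the counts also turned to higher under total-count scaling for organizer, neuronal, Wnt, retinoic acid, muscle and stress genes. It turned to lower on ribosomal centring for BMP and cell cycle genes. Organizer, stress and muscle genes turned to higher under upper-quartile scaling too, and organizer and stress genes also on the median of well measured genes. On ribosomal centring neural plate genes numbered 8 higher and 6 lower, and germline genes 4 and 1.

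Among the largest rises outside the lists was SMOC1 (BL22030), a secreted BMP modulator, 90.4-fold higher at 6.50 ± 0.48 in the authors' deposited table. Among the largest falls were AHNAK, a large scaffold protein, 291-fold lower at -8.19 ± 0.42, and TUFM (BL95063), 234-fold lower at -7.87 ± 0.44. In all 5773 genes were called at 11 hpf, 36.6% of those tested, 1893 higher and 3880 lower, so 67.2% of the calls were lower. Of these, 1820 higher and 3804 lower changed at least 2-fold. The split moved with the scaling: 51.7% of calls were lower under upper-quartile scaling, 35.2% under total-count scaling and 78.7% on ribosomal centring, after shifts of -0.44, -0.98 and 0.37 in log2. Of the 16 lists 6 passed at 11 hpf, and only Nodal/Activin, epidermis and cilia passed with a preset correlation of 0.1, adjusted p = 0.0088, 0.013 and 8.7e-04 by limma's cameraPR.

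**Figure D1:**
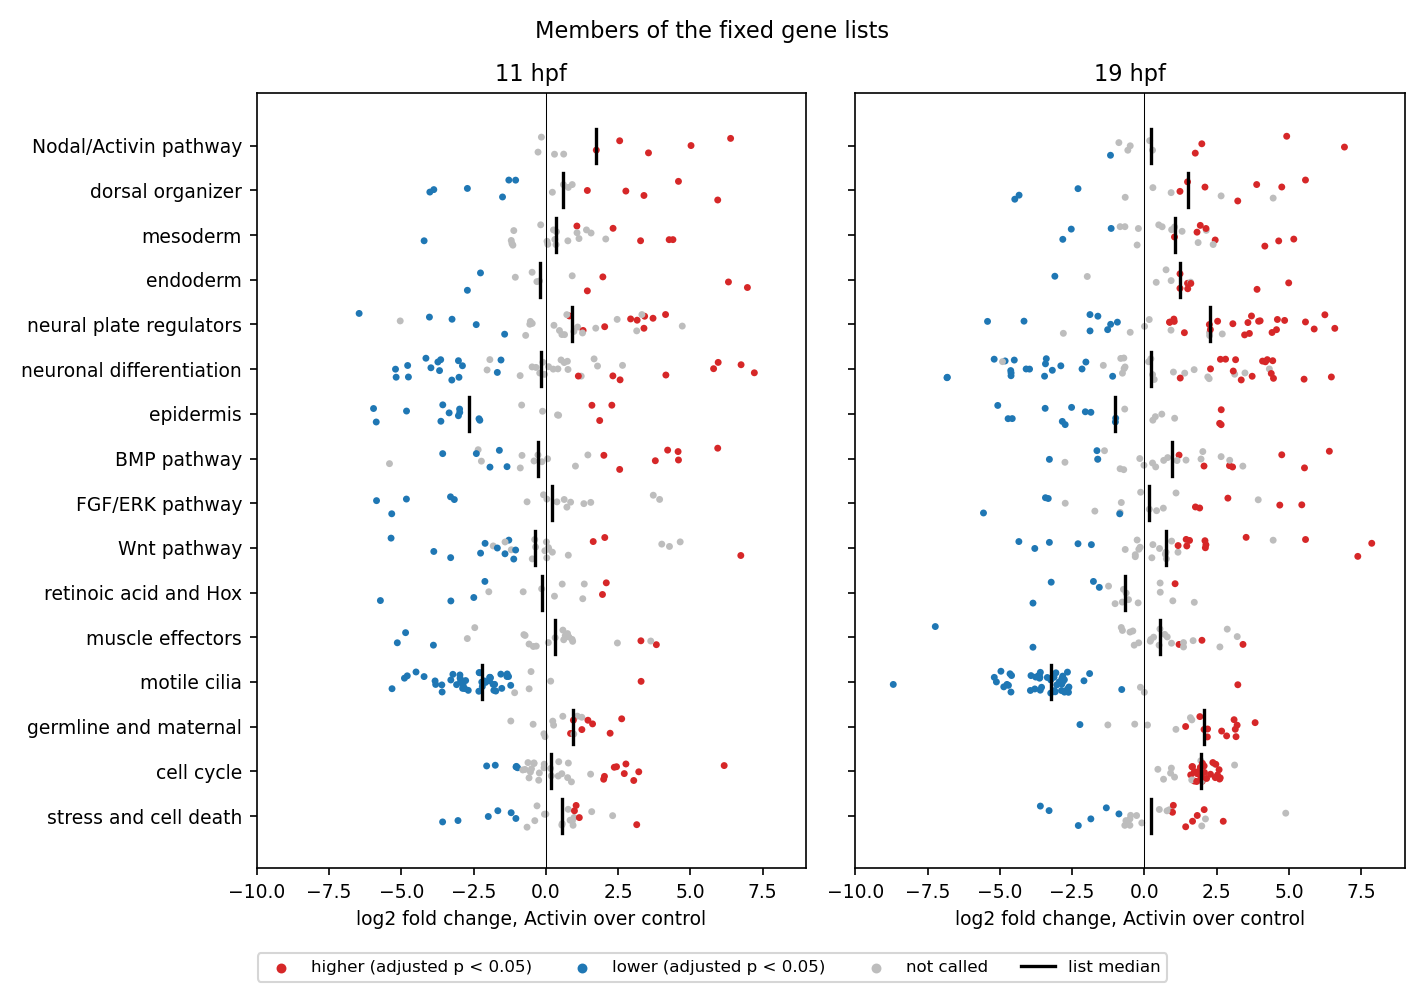
Log2 fold change of Activin over control for each member of the 16 gene lists at 11 and 19 hpf. Dots are genes colored by call and black bars are list medians, with the cilia median at -2.21 and -3.24.

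The comparison at 19 hpf put the same question to explants at the later time. In the authors' deposited table LEFTY2 was 121-fold higher, at 6.92 ± 0.43, and CHRD 26.9-fold higher, at 4.75 ± 0.37. Neural plate regulators rose, 23 of 39, with OTX2 47.4-fold higher at 5.57 ± 0.31 and FEZF2, a forebrain zinc finger gene, 75.5-fold higher at 6.24 ± 0.39. Cell cycle genes rose, 25 of 35, among them MKI67, a marker of proliferating cells, 6.15-fold at 2.62 ± 0.36. Motile cilia genes fell, 46 of 49, with DNAH5 (BL15852), an axonemal dynein, 31.2-fold lower at -4.96 ± 0.35.

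Of 10 Nodal/Activin pathway genes 4 rose and 1 fell, also when adjusted over the list alone, with limma's cameraPR, Benjamini-Hochberg adjusted p = 0.041, but not its rank version, adjusted p = 0.27, a preset correlation of 0.05, adjusted p = 0.10, or a background of genes with a symbol, adjusted p = 0.058. FST, an Activin-binding protein, lay at 4.92 ± 0.80, SKI at 1.98 ± 0.35 and SMAD3, an effector of Activin, at 1.76 ± 0.49 in the authors' deposited table. The gene that fell was FOXH1, a SMAD partner, at -1.17 ± 0.35, named after its value was seen. The median of 0.23 turned to -0.82 on ribosomal centring. Organizer genes rose more often than they fell, 7 against 3 of 15, and 8 against 3 adjusted over the list alone. GSC was 14.7-fold higher at 3.88 ± 0.52, while PRDM1, a zinc finger regulator, fell (-4.34 ± 0.31) and SHH (-4.48 ± 0.40). The organizer list passed limma's cameraPR, Benjamini-Hochberg adjusted p = 0.041, but not its rank version, adjusted p = 0.075, a preset correlation of 0.05, adjusted p = 0.11, or a background of genes with a symbol, adjusted p = 0.058. Its median of 1.49 kept its sign under all 5 scalings. Neither list is independent evidence of direction, since LEFTY2, CHRD and GSC set the reading of the sign.

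Mesoderm genes rose, 8 against 3 lower of 24, also when adjusted over the list alone. FOXD3 rose by 5.16 ± 0.38, SNAI2 by 4.64 ± 0.34 and TCF15 (BL21142), a somite regulator, by 4.16 ± 0.35. T (BL23557) rose by 1.04 ± 0.40, a value that became -0.0106 on ribosomal centring, and T (BL23554), at 1.04 ± 0.72, was not called. The list passed limma's cameraPR, Benjamini-Hochberg adjusted p = 0.0027, and its rank version, adjusted p = 0.035, but not with a preset correlation of 0.1, adjusted p = 0.13, and its median of 1.04 turned to -0.0086 on ribosomal centring. Of 13 endoderm genes 7 rose and 1 fell, also when adjusted over the list alone. NKX2-1, of the anterior endoderm and brain, lay at 4.99 ± 0.55, FOXA1 at 1.49 ± 0.45 and FOXA2 at 1.23 ± 0.42 in the authors' deposited table, while GATA4, an endodermal regulator, fell (-3.10 ± 0.32). Endoderm passed limma's cameraPR, Benjamini-Hochberg adjusted p = 0.048, and its rank version, adjusted p = 0.023, but not with a preset correlation of 0.05, adjusted p = 0.11, or a background of genes with a symbol, adjusted p = 0.069. Its median of 1.23 kept its sign under all 5 scalings but was 0.18 on ribosomal centring, with 2 genes higher and 2 lower.

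Neural plate regulators rose, 23 against 8 lower of 39, also when adjusted over the list alone. ZIC1 lay at 3.999 ± 0.31 and EN2, a midbrain homeobox gene in vertebrates, at 5.87 ± 0.53 in the authors' deposited table, while SIX3 fell (-1.88 ± 0.33). SOX2 rose by 0.87 ± 0.31 (BL03503) and 1.38 ± 0.36 (BL16400), lay at 0.16 ± 0.32 for BL16399, not called, and SOX1 rose by 1.02 ± 0.35. On ribosomal centring SOX2 (BL03503) and SOX1 turned to -0.179 and -0.0323, and SOX2 (BL16399) to -0.884, a call for lower by the Wald test, Benjamini-Hochberg adjusted p = 0.012. The list passed limma's cameraPR, Benjamini-Hochberg adjusted p = 1.1e-06, and its rank version, adjusted p = 4.3e-04, and its median of 2.25 kept its sign under all 5 scalings. Neuronal differentiation genes split again, 16 higher and 18 lower of 53, and 18 and 20 adjusted over the list alone, with limma's cameraPR, Benjamini-Hochberg adjusted p = 0.43. NEUROG3 was 88.2-fold higher at 6.46 ± 0.36 and ELAVL4 13.2-fold higher at 3.72 ± 0.30, while the glutamate transporter SLC17A6 (BL19507) fell (-6.83 ± 0.47) and NEUROG2 (BL17845) (-4.82 ± 0.37). The neuronal median of 0.22 had the opposite sign to the mean of -0.02, and turned to -0.83 on ribosomal centring.

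Epidermis genes numbered 3 higher and 11 lower of 19, also when adjusted over the list alone, and the list did not pass limma's cameraPR, Benjamini-Hochberg adjusted p = 0.19. KRT5, a keratin, fell (-4.72 ± 0.40), KLF5 (-3.43 ± 0.40) and DLX1 (-2.52 ± 0.30), while TBX2 (BL14067) rose by 2.60 ± 0.31. TFAP2D lay at -2.74 ± 0.39, GATA2 at -2.84 ± 0.37 and KRT8 (BL15060) at -4.57 ± 1.52 in the authors' deposited table, the last with an error far above the median of 0.33 for abundant genes. The epidermal median of -1.01 kept its sign under all 5 scalings but was -0.15 under total-count scaling, with 6 genes higher and 9 lower. Of the motile cilia genes 46 fell and 1, DNAH9 (BL14190), rose by 3.23 ± 1.16, also when adjusted over the list alone. TPPP3, a tubulin-binding protein, fell (-8.69 ± 0.60), TEKT3 (-4.86 ± 0.35), DNAH3 (-4.62 ± 0.32) and FOXJ1 (-1.90 ± 0.33). The cilia list passed limma's cameraPR, Benjamini-Hochberg adjusted p = 6.8e-27, and its rank version, adjusted p = 2.6e-15, and its median of -3.24 stayed negative under all 5 scalings.

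Germline and maternal genes rose, 12 of 19, also when adjusted over the list alone. DDX4, an RNA helicase of germ cells, was 8.57-fold higher at 3.10 ± 0.34 and NANOS2 lay at 2.67 ± 0.33 in the authors' deposited table. The 1 gene that fell, named after its value was seen, was PIWIL1 (BL97334) at -2.23 ± 0.35. Their list passed limma's cameraPR, Benjamini-Hochberg adjusted p = 5.4e-04, and its rank version, adjusted p = 4.3e-04, but not with a preset correlation of 0.1, adjusted p = 0.053. Its median of 2.06 kept its sign under all 5 scalings. Of the cell cycle genes 25 rose and 0 fell, and 26 rose adjusted over the list alone. TOP2A, a topoisomerase of dividing cells, was 6.05-fold higher at 2.60 ± 0.34, CCND2, a cyclin, lay at 2.58 ± 0.34 and CCNB2, a mitotic cyclin, at 2.45 ± 0.35 in the authors' deposited table. This list passed limma's cameraPR, Benjamini-Hochberg adjusted p = 5.2e-07, and its rank version, adjusted p = 4.5e-10, and its median of 1.956 kept its sign under all 5 scalings, with 11 members higher on ribosomal centring.

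BMP pathway genes numbered 7 higher and 3 lower of 28 at 19 hpf, also when adjusted over the list alone, and passed limma's cameraPR, Benjamini-Hochberg adjusted p = 0.017, but not its rank version, adjusted p = 0.052, or a preset correlation of 0.05, adjusted p = 0.10. The members that rose included the antagonist CHRD and the ligand BMP2 (BL21413) by 5.53 ± 0.72. Since CHRD helped to set the reading of the sign, this list is not fully independent evidence of direction either. BMP2 (BL12966) fell (-1.61 ± 0.36), BMP2 (BL07350) lay at -2.75 ± 1.35 and BMP4 at -1.38 ± 0.62 in the authors' deposited table, the last pair not called. The BMP median of 0.96 turned to -0.0842 on ribosomal centring. Wnt genes numbered 11 higher and 5 lower of 31, with limma's cameraPR, Benjamini-Hochberg adjusted p = 0.060, and the receptor FZD1 rose by 5.57 ± 0.44 while NOTUM fell (-4.34 ± 0.58). FGF/ERK genes numbered 5 higher and 4 lower of 19, with limma's cameraPR, Benjamini-Hochberg adjusted p = 0.51, with SPRY2, a feedback inhibitor, higher by 1.91 ± 0.34 and FGFR3 lower (-5.57 ± 0.46). Retinoic acid and Hox genes numbered 1 higher and 4 lower of 16, and 0 and 4 adjusted over the list alone, with limma's cameraPR, Benjamini-Hochberg adjusted p = 0.57, and ALDH1A2 (BL09708) fell (-3.22 ± 0.36). Muscle genes numbered 3 higher and 2 lower of 25, and 2 and 2 adjusted over the list alone, with limma's cameraPR, Benjamini-Hochberg adjusted p = 0.79, and TTN (BL96427), titin, fell (-7.23 ± 0.32). Stress genes numbered 7 higher and 6 lower of 26, with limma's cameraPR, Benjamini-Hochberg adjusted p = 0.50, with HSPH1, a chaperone, higher by 2.72 ± 0.34 and ATF3, a stress response factor, lower (-3.60 ± 0.38). Medians of Wnt, FGF, muscle, neuronal and stress genes turned negative on ribosomal centring, and that of retinoic acid genes turned positive under total-count scaling. The larger side of the counts turned to lower on ribosomal centring for Nodal/Activin, BMP, FGF, Wnt, muscle and stress genes. It turned to higher under total-count scaling for neuronal and retinoic acid genes. For neuronal genes it also turned to higher under upper-quartile scaling and on the median of well measured genes. On ribosomal centring organizer and mesoderm genes numbered 5 higher and 4 lower each, neural plate genes 17 and 11, and germline genes 8 and 3.

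Among the largest rises outside the lists was TECTA, an extracellular matrix gene, 171-fold higher at 7.42 ± 0.37 in the authors' deposited table. APOB, a lipid carrier, lay at 6.58 ± 0.68. In all 7768 genes were called at 19 hpf, 46.4% of those tested, 3128 higher and 4640 lower, so 59.7% of the calls were lower. Of these, 2926 higher and 4490 lower changed at least 2-fold. Under total-count scaling 37.1% of calls were lower, under upper-quartile scaling 44.8% and on ribosomal centring 85.2%, after shifts of -0.86, -0.54 and 1.05 in log2. Of the 16 lists 9 passed at 19 hpf, and with a preset correlation of 0.1 only neural plate, cilia and cell cycle passed, adjusted p = 0.028, 4.2e-07 and 0.023 by limma's cameraPR.

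**Figure D2:**
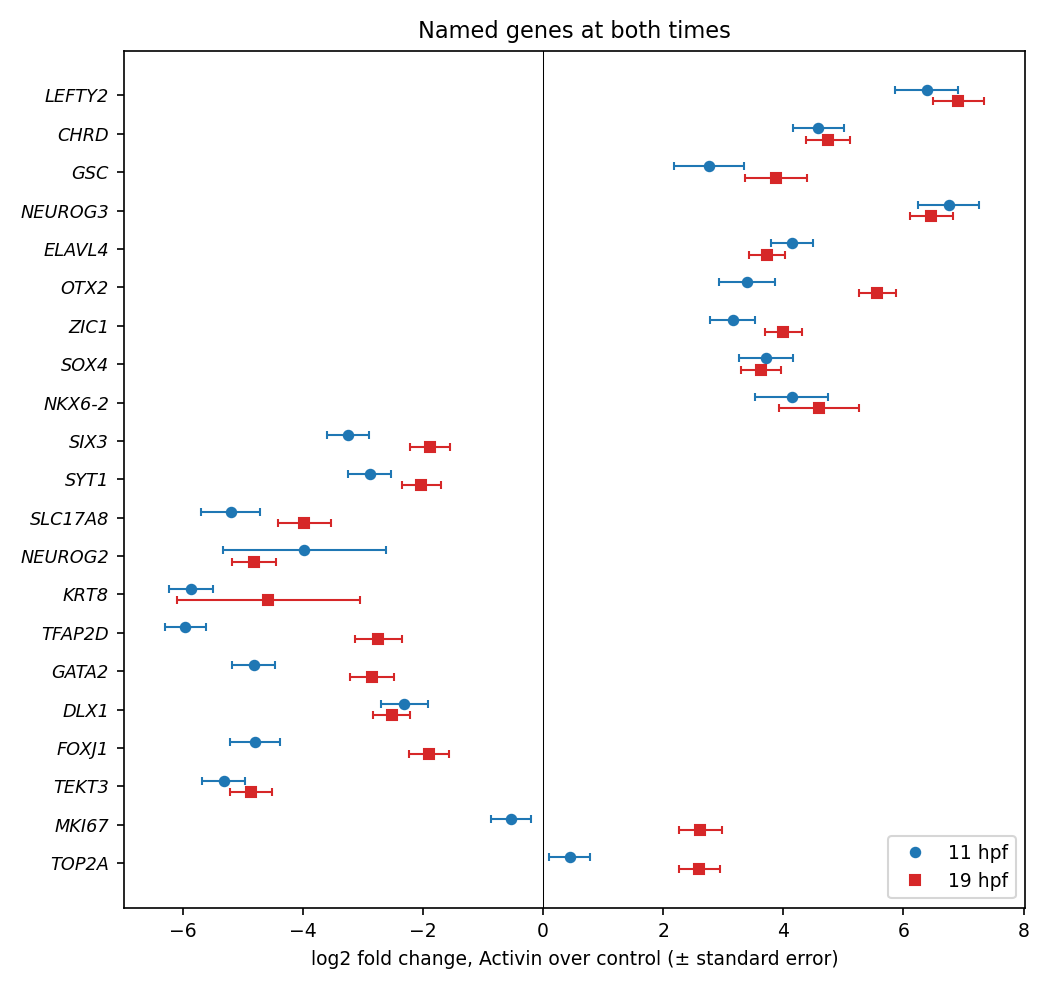
Log2 fold change of Activin over control for 21 named genes at 11 and 19 hpf, with bars of 1 standard error from the authors' tables. LEFTY2 lies at 6.39 and 6.92, and FOXJ1 at -4.79 and -1.90.

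The responses at 11 and 19 hpf were then compared gene by gene. The adhesion gene NCAM2 differed most clearly among named genes with a more positive response later, -0.35 ± 0.33 at 11 hpf against 4.89 ± 0.31 at 19 hpf in the authors' deposited table. RAX, an eye field homeobox gene, was -6.60 ± 0.39 and then -1.18 ± 0.30. RUNX1T1, a corepressor, went from -0.89 ± 0.33 to 3.51 ± 0.36, the first value turning to 0.0888 under total-count scaling. In the other direction, TTN (BL96427) was 0.67 ± 0.75 and then -7.23 ± 0.32, and PXDN, a peroxidase of the matrix, -1.33 ± 0.69 and then -7.99 ± 0.37. Fold changes of the 13528 shared genes correlated with Pearson's r = 0.691 and Spearman's rho = 0.631 across genes, which are not independent replicates. Genes higher at both times numbered 966, where independent lists would share 394.6, and genes lower at both times 2435, where they would share 949.5. Genes higher at 11 and lower at 19 hpf numbered 69, against 516.5 for independent lists, and the reverse 114, against 725.4. These numbers for independent lists take every gene as equally likely to be called. Calls rose with abundance, from 13.3% of genes under 20 counts to 61.8% at 1000 or more at 11 hpf. At 19 hpf the range was 15.3% to 71.0%, so shared abundance can raise an overlap above those numbers. The Wald test of the difference, Benjamini-Hochberg adjusted, called 2268 genes, 1362 more positive and 906 more negative at 19 hpf. On ribosomal centring these became 687 and 2047, so the split by direction depends on the scaling. Whether a list as a whole responded differently at both times was not tested. In simulated data the test found 16% of log2 differences of 2. Far fewer genes changed there than were called here, so recovery in the real data may be higher. Genes not called may still differ.

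**Figure D3:**
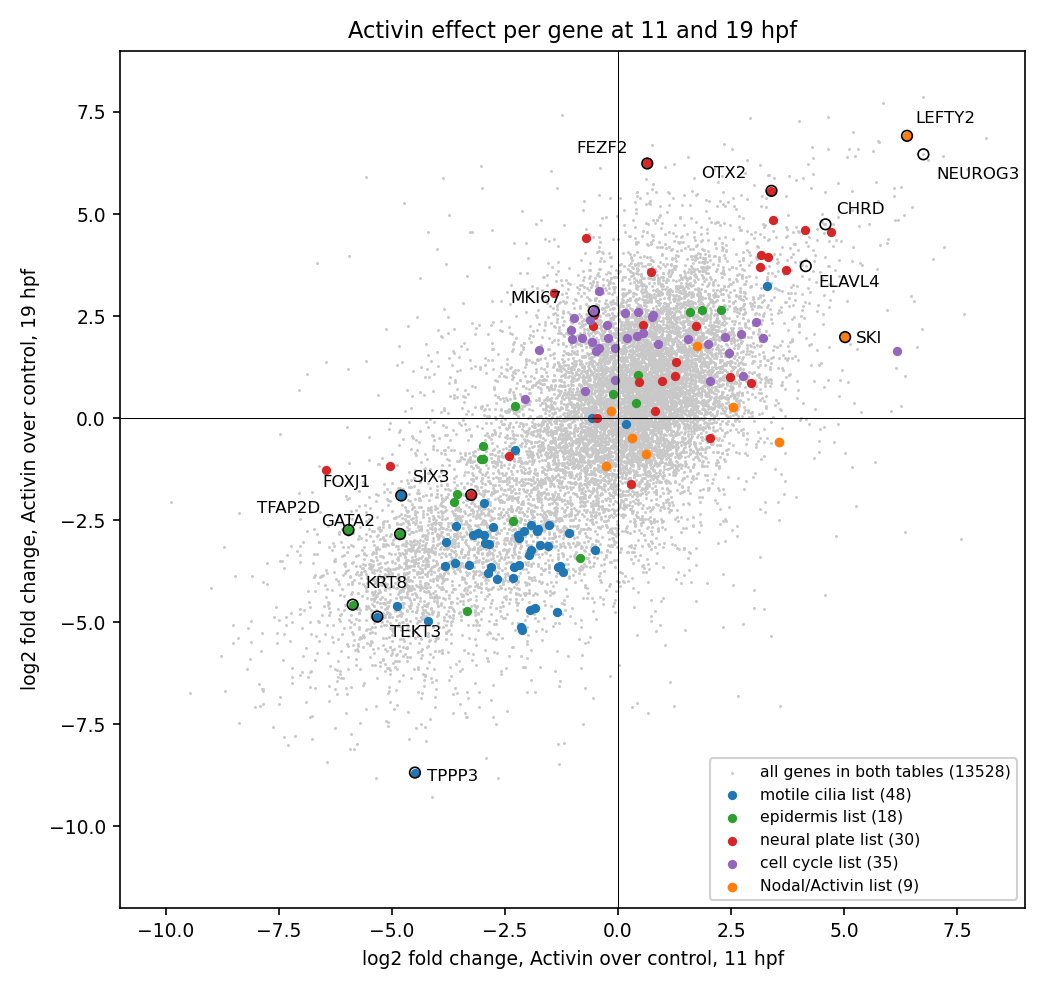
Log2 fold change of Activin over control at 11 hpf (x axis) against 19 hpf (y axis) for 13528 genes. Colored points are members of the cilia, epidermis, neural plate, cell cycle and Nodal/Activin lists, and r is 0.691 across genes.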

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

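The test of the difference between times, the tests of scaling and housekeeping families, and those of transcript decline and of a loss of cells, were chosen after the results were seen. By the Wald test of the difference, Benjamini-Hochberg adjusted below 0.05, 54 of the 134 named genes in both tables responded differently between times. Over all shared genes the test called 2268 of 13528. The named genes were partly chosen by the smallest p of this test or by large effects, which can raise their share. Values below are log2 differences, 19 minus 11 hpf, from the authors' deposited tables, and each passed that test at the authors' scaling. Ribosomal centring subtracts 0.37 at 11 hpf and 1.05 at 19 hpf, which makes each difference less positive or more negative. Small positive differences, such as those of SIX3, HEY2, HSPD1, HSPH1, KLF2, DKK3, FOXD3, BAMBI, GAD2 and GATA2, may not pass there. The same holds for positive differences with wide errors, such as those of PI16, HSPA8 and HHEX. The test was rerun on that centring for counts over all shared genes only, and which named genes still passed was not read out.

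Named by the rule for the difference itself, NCAM2 (5.24), RAX (5.42), CAPRIN2 (5.42), FJX1 (5.23) and RUNX1T1 (4.40) were more positive at 19 hpf. C20orf194 (-7.89), TTN (-7.90), UCP2 (-4.65), TRIM36 (-5.27) and PXDN (-6.66) were more negative.

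Neural and organizer regulators with a more positive response at 19 hpf were FEZF2 (5.59) and OTX2 (2.18), and PRDM1 (-2.84) was more negative. SIX3 (1.36) was lower at both times, less so at 19 hpf. Nodal/Activin pathway genes SKI (-3.04), CFC1 (-4.12) and SMAD6 (-2.27) were more negative at 19 hpf. Of mesoderm and endoderm genes, EVX2 (3.999), HEY2 (1.37), FOXD3 (1.89), CDX4 (3.01) and HHEX (3.64) were more positive, and RIPPLY2 (-2.45) more negative. Epidermal TFAP2D (3.22), GATA2 (1.98) and KLF2 (1.58) were less strongly lowered at 19 hpf, whereas KLF5 (-2.60) was more so. The cilia regulator FOXJ1 (2.90) was also less lowered at the later time. Signalling genes FZD1 (3.93) and TCF7L2 (1.91) were more positive, and the receptor RARB (-1.41) more negative. FGFR1 (2.44), BAMBI (1.92) and DKK3 (1.58) were lower at both times, less so at 19 hpf.

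Cell cycle and germline genes CCNB2 (3.42), MKI67 (3.15), CCND2 (2.42), TOP2A (2.15), DDX4 (2.15) and TDRD6 (2.29) had more positive responses at 19 hpf. Stress genes HSPA8 (4.08), HSPH1 (1.68) and HSPD1 (1.498) were more positive, and ATF4 (-3.62), ATF3 (-4.15) and HSP90B1 (-1.98) more negative. Of these, HSPA8 was lower and ATF4 higher at 11 hpf, and neither was called at 19 hpf. Further values were 3.03 for AHNAK, 1.89 for GAD2, 3.44 for PI16, 2.73 for TGM1 (BL09044), -6.17 for TGM1 (BL95848), -3.79 for CKM, -9.13 for TRPM1 and -5.41 for PTH1R. PI16 and TGM1 (BL09044) at 11 hpf, and TGM1 (BL95848) and PTH1R at 19 hpf, had a rebuilt Activin mean under the floor of 3 counts, so these sizes are not readable as folds.

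More genes were called lower than higher at both times. An offset in the authors' scaling stays open, since each scaling moves all genes alike and the lower share followed it both ways: at most 37.1% under total-count scaling, but 78.7% and 85.2% at 11 and 19 hpf on ribosomal centring. The biological alternative, a shift in cell types under Activin, was not tested. Depth-normalized counts cannot show a uniform change in RNA output per explant.

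Cell cycle genes were higher at 19 hpf, 25 of 35. The tables argue against a rise shared with cytosolic ribosomal proteins as the whole cause. The cell cycle median exceeded theirs by 0.907, with a 95% interval of 0.747 to 1.08 over resampled genes. Such intervals treat genes as independent and do not measure the spread between libraries. A rise shared with other housekeeping families stays open, since the list exceeded proteasome subunits by 0.196 (-0.0016 to 0.503) and RNA polymerase subunits by 0.452 (-0.504 to 0.679), but mitochondrial ribosomal proteins by 0.742 (0.336 to 0.923), NADH dehydrogenase subunits by 2.15 (1.87 to 2.48) and V-type ATPase subunits by 2.30 (2.01 to 2.55). Slower decline of transcripts abundant at 11 hpf could not be told apart from renewed expression. Of the 25 genes, 72% had an Activin mean between both control means. Since these genes were chosen as called higher at 19 hpf, only the upper bound could fail. That bound lay far off, as control levels were a median of 3.93 in log2 higher at 11 than at 19 hpf. These levels also come from separately normalized tables. A treatment effect on proliferation may also account for the pattern, and was not tested.

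Motile cilia genes at both times and epidermal genes at 11 hpf were lower in Activin, while the epidermal list at 19 hpf, 11 lower of 19, did not pass limma's cameraPR, Benjamini-Hochberg adjusted p = 0.19. An offset in scaling is argued against for cilia genes, of which at least 62.5% stayed lower under every scaling tried, and for epidermal genes at 11 hpf, at least 61.1%. For the epidermal genes lower at 19 hpf it stays open, since under total-count scaling 47.4% were lower, 9 against 6 higher of 19. A single loss of cells that alone express these genes would give 1 shared fold. The called-lower members of both lists, pooled, had a spread beyond standard errors of 1.01 in log2 SD at the time where it was smaller. Different losses of ciliated and epidermal cells could also give that spread. It therefore argues only against 1 loss common to both lists. A separate loss for each list, loss of cells where the genes are also expressed elsewhere, or lower expression per cell, may each remain, and none was tested.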

How the results depend on the processing

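Scalings, preset correlations, the rank test, symbol-only background, mean filter and the 0.01 threshold for the difference were chosen after seeing the data. No paired analysis was possible because the tables hold no values per library, and for the same reason TMM, RLE, DESeq2 and filter refits, leaving out replicates, the replicate block, pseudocounts and an estimated correlation were not run. Of 206 named gene values, 6 changed sign on ribosomal centring. At 19 hpf SOX2 became -0.179 (BL03503) and, called lower, -0.884 (BL16399), SOX1 -0.0323, and T -0.0106 (BL23557) and -0.00647 (BL23554), and at 11 hpf T (BL23557) became -0.302. All further sign changes were at 11 hpf. Under total-count scaling RUNX1T1 became 0.0888, NCAM2 0.628 and T (BL23554) 0.798, and under upper-quartile scaling NCAM2 became 0.0901 and T (BL23554) 0.259. On the median of all genes T (BL23557) became -0.00644, and on that of well measured genes T (BL23554) became 0.0222. Of the values that changed sign, only SOX2 (BL03503), SOX1, T (BL23557) at 19 hpf and RUNX1T1 were called in the authors' tables. With the sign kept, calls were lost for 13 values on ribosomal centring, 12 under total-count and 5 under upper-quartile scaling, 2 and 3 on the medians, and 16 at an adjusted p below 0.01. Genes called higher at 11 hpf became 3036 (upper quartile) and 4820 (total count). At 19 hpf ribosomal centring gave 1260 higher and 7255 lower, and total-count scaling 5653 higher. The difference test gave 687 more positive and 2047 more negative on ribosomal centring, and 1321 genes (820 and 501) at an adjusted p below 0.01, which only tightens the threshold. Lists passing became 3 and 3 at 11 hpf, and 5 and 3 at 19 hpf, with preset correlations of 0.05 and 0.1, which widen the test's error. A background of genes with a symbol ended 4 list calls, cell cycle at 11 hpf and endoderm, Nodal/Activin and organizer at 19 hpf. Direction turned without a call for FGF/ERK and neuronal genes at 11 hpf in the rank version of limma's cameraPR, Benjamini-Hochberg adjusted p = 0.964 and 0.798. It also turned for muscle genes at 19 hpf with members of at least 1 log2 CPM, adjusted p = 0.628. For the other values the cause was not tested. Low counts limit precision, with a median standard error of 1.604 under 20 counts at 11 hpf.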

Other observations

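The 12 gene families here were chosen after the values were seen, and no family was tested as a set. In the authors' deposited tables keratins, structural proteins of epithelia, all fell, 5 of 5 at 11 hpf and 8 of 8 at 19 hpf, with medians of -5.86 and -4.89 that held under all 5 scalings. Transglutaminases, which crosslink proteins of the epidermis, numbered 1 higher and 2 lower of 6 at 11 hpf and 0 and 9 of 10 at 19 hpf, and their median stayed negative under all 5 scalings. Intraflagellar transport genes, which build cilia, numbered 0 higher and 10 lower of 11 at 19 hpf, with a median of -2.54 that stayed negative under all 5 scalings, and 4 lower of 10 at 11 hpf, where the median of -0.62 turned to 0.36 under total-count scaling. Axon guidance genes (semaphorins, plexins, slits, robos and netrins) numbered 8 higher and 1 lower of 16 at 11 hpf and 8 and 3 of 18 at 19 hpf, with medians of 2.39 and 2.50 that kept their sign under all 5 scalings, though 5 were higher and 4 lower at 19 hpf on ribosomal centring. Mucins numbered 1 higher and 3 lower of 10 at 11 hpf and 1 and 4 at 19 hpf, with negative medians under all 5 scalings.

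Proteasome subunits numbered 15 higher and 0 lower of 34 at 11 hpf and 31 and 1 of 36 at 19 hpf, with a median of 1.76 at 19 hpf. On ribosomal centring 5 and 13 members were higher at 11 and 19 hpf. Mitochondrial ribosomal proteins numbered 6 higher and 0 lower of 63 at 11 hpf, RNA polymerase subunits 5 and 1 of 22, and cytosolic ribosomal proteins 5 and 1 of 62. Under total-count scaling these became 37 and 0, 13 and 0, and 57 and 0, and on ribosomal centring 3 and 1, 2 and 1, and 0 and 3. At 19 hpf these counts were 35 and 0 of 63, 12 and 0 of 23, and 53 and 0 of 62. On ribosomal centring, which fixes the cytosolic median at 0, they fell back at 19 hpf to 7 and 0, 7 and 2, and 3 and 0. NADH dehydrogenase subunits numbered 7 higher and 1 lower of 29 at 11 hpf and 1 and 3 of 27 at 19 hpf, with a median that turned positive under 3 scalings at 19 hpf. On ribosomal centring 0 were higher and 1 lower at 11 hpf and 0 and 20 at 19 hpf, and under total-count scaling 19 and 0, and 11 and 0. V-type ATPase subunits numbered 0 higher and 2 lower of 14 at 11 hpf and 0 and 1 at 19 hpf. On ribosomal centring 3 and 12 were lower, and under total-count scaling 5 and 3 were higher and 0 lower, with the 11 hpf median turning from -0.049 to 0.93. Nicotinic and glutamate receptor subunits numbered 4 higher and 9 lower of 32 at 11 hpf and 2 and 7 of 35 at 19 hpf, with medians that changed sign between scalings.

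KRT8 (BL15060) had the highest mean over both treatments at both times. It held 2.12% of rebuilt control counts and 0.0716% of Activin counts at 11 hpf, where H3F3A held 1.16% of Activin counts, and 5.27% and 0.402% at 19 hpf. At 19 hpf the 20 most abundant genes of each group, taken separately, held 23.1% of control counts and 8.58% of Activin counts. Of 2112 genes with at least 1000 counts at 19 hpf, 3 had a standard error of 1 or more, among them KRT8 at 1.52 and OVCH1 at 1.08.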
